A study of Glycine max with 8 samples.

How the data were processed

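RNA from the first trifoliate leaf and from the root of soybean (Glycine max, cultivar Williams 82) was sequenced by the authors as paired-end reads, per the labels. Plants grew hydroponically and received a nutrient solution with 0.38 µM zinc sulphate or with none (0 µM) for 12 days, per the labels. The 8 libraries form 4 groups of 2: zinc-sufficient leaf, zinc-deficient leaf, zinc-sufficient root and zinc-deficient root. Each library was placed in its group from its title. The labels do not state that the 2 libraries of a group came from separate plants or tanks, so p-values measure the spread between these samples, which may be technical.

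The submitters' processing notes name FastQC, Bowtie2, TopHat, Cufflinks and Cuffdiff. Their versions, settings and roles, the gene annotation and the genome build are not given in the sources used here. The reads were aligned to a soybean reference genome, per the labels. The authors deposited a table for each tissue, with 40034 loci for leaf and 42156 loci for root. Each table gives an FPKM value (fragments scaled to transcript length and library size) per library, per the file headers, and the authors' own FPKM per condition. It also holds the authors' log2 fold change of the deficient over the sufficient condition and the authors' unadjusted p-value, per the file headers. The condition FPKM is on a scale of its own: its median ratio to the plain mean of the replicates was 0.866 and 0.869 in leaf and 1.3 in both root groups, so levels in the authors' deposited table and levels from the replicate columns are not interchangeable. The authors' call of a differentially expressed locus matched, for every locus in both tables, a test status of OK with an unadjusted p-value under 0.05 and an absolute log2 fold change of at least 1. Loci with status NOTEST numbered 10416 in leaf and 8459 in root. A soybean gene ID was paired with 38787 leaf and 40904 root loci, and 943 and 944 of the loci joined several genes. Gene names are the descriptions that the tables pair with the IDs, spelled as there. Coordinates are those of the tables. No exon, intron or UTR annotation of that build was used here.

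FPKM values carry no read counts, so the depth of each library is unknown and no counting interval is given. Low values were inspected for steps of whole fragments. In the deficient leaves, 31 of 42 uncalled loci that were listed at 0 in both sufficient libraries stood near a base ratio, fitted to these same loci, times a ratio of whole numbers up to 3, but in the sufficient leaves only 6 of 25 such loci did, so read counts were not recovered. A value of exactly 0 can be a failed estimate, and loci with a group at 0 are given as listed at 0, with no fold change. The tissues came in separate tables, which may have been normalised separately, and each was tested within its own table. Where both tissues entered 1 model, the difference of their fold changes was tested, or, in the fit on all 8 libraries, the fold change within each tissue; levels were not compared across tissues.

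The following choices were made before the data were examined. Values were transformed to log2(FPKM + 0.5), and loci with a mean FPKM of at least 1 over the 4 libraries of a tissue were tested. This left 29014 leaf and 31549 root loci. Fold changes on this scale understate the change of genes with low FPKM. Zinc-deficient minus zinc-sufficient was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), with Benjamini-Hochberg adjustment over all tested loci and a threshold of 0.05. The fit had no block, since no label says that replicate numbers link plants. The difference between tissues was tested as an interaction over all 8 libraries on 25557 loci tested in both. A permutation test of 2 libraries against 2 cannot reach a p-value under 0.05, so none was used for single genes. Overlap of calls between the tissues was set against independent lists with a hypergeometric test. The comparisons share no library.

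Gene lists were fixed at the same time from family names and Arabidopsis best hits: 24 pathway lists and 9 lists of markers for other cell types or states, 33 in all. Members were then matched by their descriptions alone, and the best hits were not applied. Lists may thus lack genes that were fixed by locus, as for the iron deficiency response and the ferritins. Counts of members cover only genes whose description matched. No member was found by description for group F bZIP transcription factors, root endodermis and guard cells, so these lists have no result. The xylem list had too few expressed members in leaf, where lists needed at least 3. That left 29 lists in leaf and 30 in root. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a tissue. It was tested again with an estimated correlation and with the directional test of fry. Fry's mixed test, which counts changes in either direction, passed some lists in both tissues and is not counted here. An estimated correlation leaves camera only the few residual degrees of freedom of 4 libraries. For the root ZIP list the estimate was 0.00984, near the preset, yet camera's unadjusted p went from 3.4e-07 to 0.0363. Failing there thus does not show, and does not exclude, that inter-gene correlation made a list pass. Members were counted over all genes tested and adjusted over the list alone. Among lists that did not pass, the median, the mean and the camera direction did not share a sign in leaf for ferritins, superoxide dismutases, glutathione S-transferases and pathogenesis-related proteins. In root this held for hydrogen peroxide metabolism, glutathione S-transferases, phenylpropanoid synthesis, expansins, aquaporins, vegetative storage proteins, photosystem genes, root nodules and dividing cells.

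The rule for named genes, also fixed then, took per tissue up to 8 rising and 8 falling annotated loci by log2 fold change among those past the threshold, or up to 5 by unadjusted p-value where fewer passed. It also took up to 6 members of each zinc list and up to 3 of each other list past the threshold, or the member with the highest mean FPKM, and up to 8 rising and 8 falling loci from the authors' calls. An unannotated locus was named only among the first 2 of a direction. Members past the threshold adjusted over the list alone were added to the rule after the values were seen.

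The alternatives planned were pseudocounts of 0.1 and 1, a minimum mean FPKM of 5, no filter, quantile normalisation, median-ratio scaling, eBayes without trend, robust eBayes, a fit on all 8 libraries with a pooled spread, a replicate block, and each library left out in turn. Restricting the tests to loci with status OK or to loci spanning at least 500 bp was added after the data were seen. Scripts ran on limma 3.58.1, the R package data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

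The fit was tested on simulated data that kept the mean of each real locus and drew its spread from the distribution fitted by limma, with the widest draws capped. In the simulated leaf comparison of 29011 loci, changes of 1 log2 unit were found for 0 of 67 genes, changes of 2 for 23 of 67 and changes of 4 for 56 of 66, with 3 unchanged genes called. In the simulated root comparison of 31546 loci the numbers were 0 of 67, 29 of 67 and 57 of 66, with 4 unchanged genes called. A list of 20 genes shifted by 0.8 log2 units was called by camera in both, and 0 of 30 unshifted lists were. Genes were simulated independently of each other, whereas members of some real lists vary together (estimated correlation 0.741 for photosystem genes in leaf). The simulation therefore does not test false calls for such lists. Spread was drawn equal for all 4 libraries of a locus, and steps of whole fragments were not simulated. Changes of single genes were planted only at loci with a mean log2 value above 1. False calls at loci with a group at 0, or from a deviating library such as zinc-deficient root replicate 2, were thus not tested.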

Results

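Transcript levels were measured in 8 RNA-seq libraries of soybean Williams 82, the cultivar of the reference genome, 20 days after germination. Seedlings had grown for 8 days in complete nutrient solution and then for 12 days with 0.38 µM zinc sulphate (zinc-sufficient) or without added zinc (zinc-deficient). The first trifoliate leaf and the root were each represented by 2 libraries per zinc supply. Values were FPKM computed by the authors, so sequencing depth was unknown. Summed FPKM lay between 1546424 and 1824210 in the 4 leaf libraries. In root it lay between 1051195 and 1061635 in 3 libraries and reached 5339194 in zinc-deficient root replicate 2. Loci spanning under 500 bp held 63.7% of the sum in that library and 14.3% to 15.9% in the other root libraries. Across loci, which are not independent replicates, log2 values of that library correlated with the other root libraries at Pearson r of 0.866 to 0.881, while the other root pairs reached 0.928 to 0.941 and the leaf pairs 0.926 to 0.946.

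Zinc-deficient and zinc-sufficient leaves were compared to find the transcripts that differ in the shoot after zinc withdrawal. Of 20 measured transporters of the ZIP family, which carry zinc and iron into the cytosol, 2 rose over all genes tested. Glyma.13G004400, described as a zinc transporter 5 precursor (chromosome 13, 1216084 to 1220866), rose from 10.2 ± 1.15 to 415 ± 144 FPKM (SD, n = 2 each), a log2 fold change of 5.25 with an SE of 0.275 (limma, Benjamini-Hochberg adjusted p = 0.0242). Glyma.06G052000, described as iron regulated transporter 3 (chromosome 6, 3913059 to 3915097), rose from 78.1 ± 0.662 to 476 ± 76.7 FPKM (SD, n = 2 each), with a log2 fold change of 2.59, an SE of 0.156 and a limma Benjamini-Hochberg adjusted p of 0.0369. Glyma.08G346100, a DUF506 protein of unknown function (chromosome 8, 46093775 to 46094633), rose from 0.642 ± 0.0399 to 39.1 ± 12.1 FPKM (SD, n = 2 each; limma, Benjamini-Hochberg adjusted p = 0.0209). Across all loci, limma called 35 of 29014 (26 rising, 9 falling), and 2175 had an unadjusted p under 0.05 (1428 rising, 747 falling). In 29 of the 35, both libraries of 1 group were listed at 0. The 4 libraries did not overlap between groups at 39% of tested loci, where chance gives 33.3%. With any 1 of the 4 leaf libraries left out, limma called 0 of 29014 loci.

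The ZIP list had 20 measured members in leaf. Over all genes tested, 2 rose, and adjusted over the list alone 5 rose, 0 fell and 15 did not pass. Besides Glyma.13G004400 and Glyma.06G052000, these were 3 loci described as zinc transporter 1 precursors. Glyma.15G262800, in a locus joined with Glyma.15G262900 (chromosome 15, 49558107 to 49565038), rose from 1.48 ± 0.749 to 72.5 ± 34.8 FPKM (SD, n = 2 each). Glyma.20G063100 (chromosome 20, 20456758 to 20460361) rose from 12.9 ± 3.72 to 354.9 ± 132 FPKM, and Glyma.08G164400 (chromosome 8, 12943072 to 12945782) from 1.8 ± 0.18 to 59.9 ± 28.6 FPKM (SD, n = 2 each). Their list-alone adjusted p in limma lay between 0.000593 and 0.000764, against 0.06 to 0.0894 over all genes. As a set, the ZIP list was shifted upward (camera adjusted p = 0.0366), with adjusted p = 0.734 with an estimated correlation. Among 14 genes of nicotianamine synthesis and yellow stripe-like transport, which make and move a chelator of zinc and iron, 2 rose adjusted over the list alone and 0 over all genes. Nicotianamine synthase 2 (Glyma.19G228400, chromosome 19, 47988705 to 47989653) rose from 51.7 ± 2.2 to 246 ± 53.3 FPKM, and nicotianamine synthase 4 (Glyma.09G036400) from 8 ± 2.72 to 35.9 ± 0.396 FPKM (SD, n = 2 each). None of the 33 measured members of the zinc efflux and vacuolar list passed. Its member with the highest mean, PLANT CADMIUM RESISTANCE 2 (Glyma.05G236300), was at 1209 ± 284 FPKM in deficient and 1127 ± 98.3 FPKM in sufficient leaves.

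Changes were also found among genes for zinc and iron enzymes, defence and secondary metabolism. For every list in this paragraph 0 members passed over all genes, and limma's counts are those adjusted over the list alone. Of 12 superoxide dismutases, which remove superoxide, 2 fell. Both are described as Fe superoxide dismutase 2: Glyma.10G193500 fell from 929.7 ± 9.02 to 457 ± 98.3 FPKM and Glyma.20G196900 from 1201 ± 48.3 to 734 ± 54.5 FPKM (SD, n = 2 each; both adjusted p = 0.0382 over the list alone in limma). Of 19 carbonic anhydrases, zinc enzymes that interconvert carbon dioxide and bicarbonate, 1 rose, alpha carbonic anhydrase 4 (Glyma.12G175800), from 15.3 ± 0.17 to 39.2 ± 7.8 FPKM. Of 57 glutathione S-transferases 1 rose: TAU 19 (Glyma.08G174700, chromosome 8, 13957779 to 13959859) went from 93.6 ± 16.7 to 453 ± 137 FPKM. Among 55 pathogenesis-related proteins and chitinases, 3 rose (the basic chitinases Glyma.16G119200 and Glyma.01G160100, and pathogenesis-related 4, Glyma.19G245500) and 3 fell (Glyma.12G156600, Glyma.11G124500 and Glyma.10G060800). Of 32 phenylpropanoid and isoflavonoid genes 3 fell, all described as chalcone and stilbene synthases, which open flavonoid synthesis. The most abundant of them, Glyma.11G011500, went from 91.4 ± 9.09 to 44.6 ± 6.97 FPKM. Of 22 genes on the phloem marker list 3 rose, all phloem protein 2-B15, and the list did not pass as a set (camera adjusted p = 0.81). The locus joining Glyma.03G233900 and Glyma.03G234000 went from 28.6 ± 0.377 to 150.0 ± 70.4 FPKM, and Glyma.19G231000 from 2.16 ± 0.407 to 20.7 ± 12.7 FPKM. Of 28 senescence markers 2 rose (Glyma.19G211600, listed at 0 in both sufficient libraries, and Glyma.19G098500). Of 13 vegetative storage proteins 1 rose (Glyma.03G166500), and of 100 auxin-responsive genes 1 rose (Glyma.12G035300, also listed at 0 in both sufficient libraries). The deficient leaves read 9.85 and 3.87 FPKM for Glyma.19G211600 and 6.07 and 4.705 FPKM for Glyma.12G035300 (280 bp, status NOTEST). Both are among the 42 such loci not called over all genes, of which 31 stood near ratios of small whole numbers. Their rise may thus rest on few fragments.

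As whole sets, 7 of 29 lists passed in leaf with camera at the preset correlation, and 0 with an estimated correlation or with directional fry. With so few libraries, an estimated correlation left a list little room to pass. Yet of these 7 lists, only the ZIP transporters had an estimate below the preset of 0.01 (-0.0341). The others ran from 0.0574 (phenylpropanoid genes) to 0.811 (metallothioneins), with photosystem genes at 0.741. Their p-values at the preset may thus be too small. Besides ZIP transporters, the metallothioneins (7 genes, median log2 0.45) and the aquaporins (39 genes, median 0.21), which are water channels, were shifted upward. Their camera adjusted p was 0.0455 and 0.00442, with adjusted p = 0.88 and adjusted p = 0.734 with an estimated correlation. Phenylpropanoid and isoflavonoid genes (median -0.33), heat shock proteins (88 genes, median -0.08) and cytosolic ribosomal proteins (494 genes, median -0.12) were shifted downward. Their camera adjusted p was 1.22e-06, 0.0112 and 1.22e-06, with adjusted p = 0.734, adjusted p = 0.771 and adjusted p = 0.771 with an estimated correlation. Photosystem and antenna genes (137 genes, median -0.19) had a camera adjusted p of 0.00442, with adjusted p = 0.948 with an estimated correlation. Their direction rested on zinc-deficient leaf replicate 2: without it the median was 0.13 and the shift upward (camera adjusted p = 0.00874). The number of lists past the threshold was 4 without zinc-sufficient leaf replicate 1, 3 without zinc-sufficient leaf replicate 2 (0 upward, 3 downward), 4 without zinc-deficient leaf replicate 1 and 7 without zinc-deficient leaf replicate 2. The ZIP transporters and the metallothioneins did not pass with any 1 leaf library left out, and the aquaporins did not pass without zinc-sufficient leaf replicate 2 or zinc-deficient leaf replicate 1. The downward lists did not all hold either. At least 1 of them did not pass without zinc-sufficient leaf replicate 1, without zinc-sufficient leaf replicate 2, or without zinc-deficient leaf replicate 1. In zinc-sufficient leaf replicate 2, loci spanning under 500 bp held 10.4% of summed FPKM, against 15.9% to 16.9% in the other leaf libraries, and metallothionein 2A (Glyma.18G180800, 169 bp) read 98160 and 49710 FPKM in sufficient and 88560 and 77450 FPKM in deficient leaves. No member passed, over all genes or adjusted over the list alone, among these metallothioneins, aquaporins, heat shock, ribosomal and photosystem genes. The same held for 19 genes of the iron deficiency response (without CYP82C4) and 6 ferritins (without the copies of ferritin 1). It held too for 34 genes of hydrogen peroxide and ascorbate metabolism and 54 class III peroxidases. It held as well for 53 genes of jasmonate synthesis and signalling, 3 of ethylene synthesis, 44 of the phosphate starvation response and 27 of nitrate uptake and assimilation. Likewise none passed among 39 expansins and xyloglucan endotransglucosylases, 11 root hair markers, 16 nodule markers and 12 markers of dividing cells. Of 38 named leaf genes past a threshold, 7 and 5 stayed past it without zinc-sufficient leaf replicate 1 and 2, and 11 and 8 without zinc-deficient leaf replicate 1 and 2.

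Most other leaf calls were loci listed at 0 in 1 group. Among those rising, Glyma.18G061600, described as a plant peptide containing sulfated tyrosine 1 and thus a secreted signal peptide, had 14.5 and 17.1 FPKM in the deficient libraries. Glyma.11G225100 (maternal effect embryo arrest 60) had 55.1 and 43.8 FPKM, Glyma.09G121300 (a protein kinase) 22.4 and 17.6 FPKM, and Glyma.08G151300 (germin 3) 20.2 and 15.9 FPKM there. The unannotated Glyma.08G057900 (169 bp) had 356 and 419.8 FPKM and Glyma.04G223400 had 1110.2 and 432 FPKM. Among those falling, Glyma.12G009000 (ROTUNDIFOLIA like 17) had 18 and 30.3 FPKM in the sufficient libraries, and the unannotated Glyma.19G042300 and Glyma.05G186800 had 236 and 112, and 152 and 73.8 FPKM. Of the 35 calls, 19 had status NOTEST and 12 were among the authors' calls.

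The authors' deposited table called 614 leaf loci at its unadjusted threshold, 367 rising and 247 falling, of which 178 had a Benjamini-Hochberg adjusted value under 0.05 when their p-values were adjusted here. In the authors' deposited table the log2 fold change was 5.35 for Glyma.13G004400, 4.79 for Glyma.20G063100, 5.06 for Glyma.08G164400 and 2.55 for Glyma.06G052000. Both deficient libraries lay beyond both sufficient libraries at 334 of the 367 rising and 223 of the 247 falling calls in the authors' deposited table. The calls were made on these same libraries, so their selection favours such separation and it is no separate evidence. For some named loci the size of the fold rested on 1 library. For Glyma.18G050500, a cation efflux family protein, the authors' deposited table gave 8.09, while the libraries read 1.44 and 159.8 FPKM in deficient and 0.292 and 0.309 FPKM in sufficient leaves. For Glyma.01G228600, a Translin family protein, the authors' deposited table gave 11.91, from deficient libraries at 0.108 and 2200 FPKM. For the joined locus of Glyma.16G158900, Glyma.16G159000 and Glyma.16G159100, a TIR-NBS-LRR disease resistance protein, the authors' deposited table gave -7.64, from sufficient libraries at 294 and 0.95 FPKM. For the dirigent-like Glyma.03G044900, where both sufficient libraries lay above both deficient ones, the authors' deposited table gave -4.61, from 27.7 and 3.12 FPKM in sufficient and 1.01 and 0.3 FPKM in deficient leaves.

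**Figure D1:**
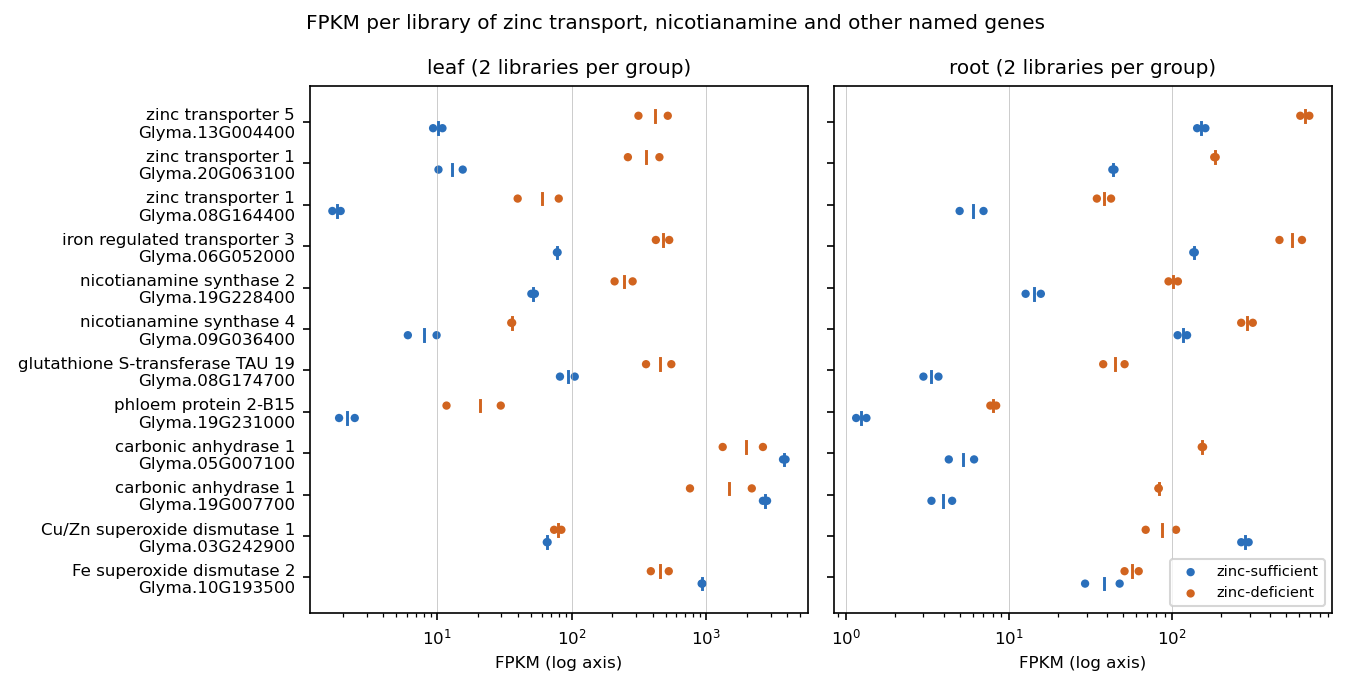
FPKM of 12 named genes in leaf and in root on a logarithmic axis, with a dot for each of the 2 libraries of a group, a vertical tick at their mean, zinc-sufficient plants in blue and zinc-deficient plants in orange. Glyma.13G004400 lies at a mean of 10.2 FPKM in sufficient and 415 FPKM in deficient leaves, and carbonic anhydrase 1 (Glyma.05G007100) at 5.21 FPKM in sufficient and 153 FPKM in deficient roots.

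In roots, the same comparison asked which transcripts differ in the organ that takes up zinc. Carbonic anhydrase 1 was higher in deficient roots at 2 copies. Glyma.05G007100 (chromosome 5, 679284 to 689557) rose from 5.21 ± 1.3 to 153 ± 1.99 FPKM (SD, n = 2 each), with a log2 fold change of 4.77 and an SE of 0.189. Glyma.19G007700 (chromosome 19, 774596 to 781808) rose from 3.93 ± 0.803 to 82.7 ± 0.221 FPKM (SD, n = 2 each), with a log2 fold change of 4.24 and an SE of 0.158. Both passed adjusted over the list alone (limma, Benjamini-Hochberg adjusted p = 0.000187), and not over all genes (adjusted p = 0.0845). Over all 31549 loci limma called 0, the smallest Benjamini-Hochberg adjusted p being 0.0637, while 2837 loci had an unadjusted p under 0.05 (1886 rising, 951 falling) and the authors' deposited table called 1011. The libraries of the 2 groups did not overlap at 43.2% of tested loci, where chance gives 33.3%. Fitted on all 8 libraries with a pooled spread, limma called 25 root loci (23 rising, 2 falling), Glyma.05G007100 among them (adjusted p = 0.0147), and without zinc-deficient root replicate 1 it called 157. Glyma.19G007700 was not among the 25 root loci called on all 8 libraries. Another transcript, XLOC_041148, was assembled at the same coordinates as Glyma.05G007100, and reads of overlapping or near-identical copies could not be told apart here.

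The ZIP transporters were the list with most members past the threshold in root. Of 22 measured, 8 rose adjusted over the list alone, 0 fell, 14 did not pass, and 0 passed over all genes. Glyma.13G004400 rose from 151 ± 12.5 to 652 ± 58.7 FPKM, Glyma.06G052000 from 136 ± 2.08 to 539.8 ± 120.3 FPKM and Glyma.20G063100 from 43.8 ± 0.941 to 183 ± 2.58 FPKM (SD, n = 2 each). Zinc transporter 4 (Glyma.04G051100, chromosome 4, 4150255 to 4151683) rose from 0.0312 ± 0.0441 to 6.26 ± 0.451 FPKM, and zinc transporter 10 (Glyma.20G022500) from 56.7 ± 14 to 157 ± 0.934 FPKM. The others were Glyma.15G262800, Glyma.08G164400 and a further zinc transporter 10, Glyma.07G223200. Their list-alone adjusted p in limma ran from 0.000925 to 0.0492. The set was shifted upward (camera adjusted p = 5.09e-06), with adjusted p = 0.803 with an estimated correlation. Of 36 zinc efflux and vacuolar transporters 4 rose adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00281, and adjusted p = 0.803 with an estimated correlation). These were heavy metal atpase 2 (Glyma.13G099600, 65.2 ± 1.43 to 117 ± 7.18 FPKM), heavy metal atpase 1 (Glyma.05G098800, 5.65 ± 0.274 to 10.5 ± 0.741 FPKM), and the cation efflux proteins Glyma.09G122600 (29.9 ± 5.42 to 69.2 ± 8.98 FPKM) and Glyma.18G050500. For the last, the deficient libraries stood at 79.5 and 646 FPKM and the sufficient libraries at 0.274 and 0.487 FPKM. Of 13 nicotianamine and yellow stripe-like genes 3 rose adjusted over the list alone and 0 over all genes. Nicotianamine synthase 2 (Glyma.19G228400) went from 14.2 ± 2.15 to 102 ± 9.54 FPKM, nicotianamine synthase 4 (Glyma.09G036400) from 116 ± 10.9 to 289 ± 33.2 FPKM and nicotianamine synthase 3 (Glyma.03G231200) from 26.3 ± 0.863 to 72.2 ± 11.6 FPKM.

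Copper/zinc superoxide dismutase 1, an enzyme with zinc in its active site, was lower in deficient roots. Of 11 superoxide dismutases 2 fell adjusted over the list alone and 0 over all genes: Glyma.03G242900 (chromosome 3, 44076361 to 44079717) from 279.9 ± 20.6 to 87.4 ± 26.1 FPKM and Glyma.19G240400 (chromosome 19, 48828032 to 48831461) from 542 ± 55 to 297 ± 24.9 FPKM (SD, n = 2 each; list-alone adjusted p = 0.0317 and adjusted p = 0.0421 in limma). Of 45 phosphate starvation genes 3 rose adjusted over the list alone and 0 over all genes: purple acid phosphatase 17 (Glyma.05G247900, 3.38 ± 0.149 to 9.21 ± 2.25 FPKM) and the SPX domain gene 2 copies Glyma.17G114700 (4.02 ± 0.669 to 9.62 ± 0.0325 FPKM) and Glyma.13G166800 (5.3 ± 0.73 to 11.1 ± 0.436 FPKM). That set was shifted upward (median log2 0.22, camera adjusted p = 0.000292, and adjusted p = 0.803 with an estimated correlation). Glutathione S-transferase TAU 19 (Glyma.08G174700) went from 3.36 ± 0.501 to 44.5 ± 9.43 FPKM and was the 1 of 56 glutathione S-transferases that rose adjusted over the list alone. Of 24 genes on the phloem marker list 2 rose, both phloem protein 2-B15 (Glyma.19G231000 and the locus of Glyma.03G233900). As a set the phloem list did not pass (camera adjusted p = 0.641). Of 30 senescence markers 2 fell (Glyma.18G056400 and Glyma.13G264000). Both counts are adjusted over the list alone, with 0 over all genes. Cytosolic ribosomal proteins (496 genes, median log2 -0.20) were shifted downward (camera adjusted p = 1.14e-12, and adjusted p = 0.803 with an estimated correlation). Thus 4 of 30 lists passed in root at the preset correlation, and 0 with an estimated correlation or with directional fry. Of 27 named root genes past a list-alone threshold, 15 and 11 stayed past it without zinc-sufficient root replicate 1 and 2, and 15 and 16 without zinc-deficient root replicate 1 and 2.

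No member passed, over all genes or adjusted over the list alone, among 23 genes of the iron deficiency response (without CYP82C4). None did among 8 ferritins (without the copies of ferritin 1). Nor did any among 33 genes of hydrogen peroxide and ascorbate metabolism, 104 class III peroxidases, 101 heat shock proteins or 73 pathogenesis-related proteins and chitinases. None passed among 55 jasmonate, 5 ethylene and 108 auxin-responsive genes. The same held for 32 phenylpropanoid, 25 nitrate, 67 expansin and xyloglucan endotransglucosylase, 40 aquaporin, 15 vegetative storage and 496 ribosomal genes, and for markers of photosynthetic cells (120 genes), root hairs (11), xylem vessels (5), nodules (28) and dividing cells (21). In the metallothioneins, small proteins that bind zinc and copper, 0 of 7 passed (median log2 2.05, camera adjusted p = 0.115). Their libraries stood apart: zinc-deficient root replicate 1 was at 0.87 to 1.7 times the sufficient mean, and replicate 2 at 4.79 to 33.2 times. For metallothionein 2A (Glyma.18G180800, 169 bp), the deficient libraries read 17720 and 605700 FPKM and the sufficient libraries 18830 and 17620 FPKM. Each of these 7 loci was called rising in the authors' deposited table.

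Outside the lists, the locus with the smallest unadjusted p among those higher in deficient roots was XLOC_041148, at 0.162 ± 0.0235 FPKM in sufficient and 36.6 ± 6.94 FPKM in deficient roots (SD, n = 2 each; limma, Benjamini-Hochberg adjusted p = 0.0845). The F-box/RNI-like protein Glyma.01G187800 and reversibly glycosylated polypeptide 3 (Glyma.06G205600) followed. Glyma.06G205600 stood at 1.52 ± 0.414 FPKM in sufficient and 39.9 ± 3.19 FPKM in deficient roots (SD, n = 2 each; limma, Benjamini-Hochberg adjusted p = 0.0933), and Glyma.01G187800 at 3.93 ± 0.0683 and 20.1 ± 0.168 FPKM (adjusted p = 0.0845 in limma). Among those lower, the ankyrin repeat protein Glyma.07G261100 stood at 42.2 ± 8 FPKM in sufficient and 2.05 ± 0.301 FPKM in deficient roots (limma, Benjamini-Hochberg adjusted p = 0.0988). The lipid-transfer-like Glyma.18G085700, the potato inhibitor I-type protease inhibitor Glyma.10G184700, CLAVATA3/ESR-RELATED 20 (Glyma.14G046400) and the unannotated Glyma.19G131100 were listed at 0 in both deficient libraries.

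The authors' deposited table called 1011 root loci, 776 rising and 235 falling, of which 396 had an adjusted value under 0.05 when their p-values were adjusted here. In the authors' deposited table the log2 fold change was 4.92 for Glyma.05G007100, 4.42 for Glyma.19G007700, 5.19 for Glyma.09G009700 (DUF506) and 5.26 for Glyma.06G257500 (S-locus lectin protein kinase). The authors' deposited table gave -4.22 for Glyma.07G261100 and -1.77 for Glyma.03G242900. Loci spanning under 500 bp made up 163 of its 776 rising and 14 of its 235 falling calls. Zinc-deficient root replicate 2 exceeded both sufficient libraries at 762 of the 776 rising loci, and replicate 1 at 623. Arabinogalactan protein 14 (Glyma.16G153600, 169 bp), with 4.94 in the authors' deposited table, read 176 and 11590 FPKM in the deficient and 231 and 169.8 FPKM in the sufficient libraries.

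**Figure D2:**
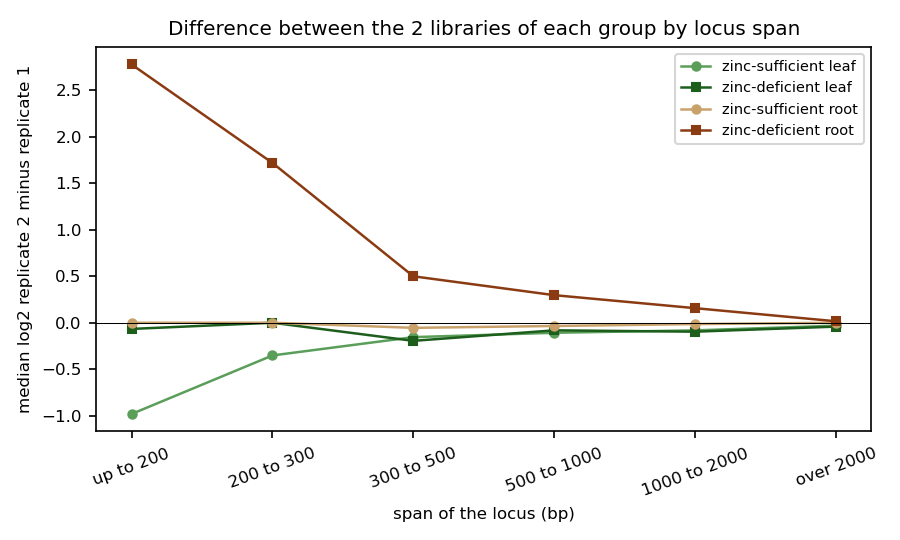
Median log2 difference of replicate 2 minus replicate 1 within each of the 4 groups, by the span of the locus in 6 bins. In zinc-deficient root it is 2.78 for loci up to 200 bp and 1.72 from 200 to 300 bp, while in zinc-sufficient root both are 0 and in zinc-sufficient leaf they are -0.982 and -0.352.

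The responses of leaf and root were then set against each other. Carbonic anhydrase 1, which rose in roots adjusted over the list alone, passed no test in leaf. For Glyma.05G007100 the leaf means were 1977 ± 925 FPKM in deficient and 3794 ± 116 FPKM in sufficient plants (SD, n = 2 each; limma, Benjamini-Hochberg adjusted p = 0.664, and adjusted p = 0.43 over the list alone). The difference of log2 fold changes, root minus leaf, was 5.79 with an SE of 0.466 (limma, Benjamini-Hochberg adjusted p = 0.0902). For the zinc transporter Glyma.13G004400 this difference was -3.14 with an SE of 0.345 (limma, Benjamini-Hochberg adjusted p = 0.186). Of 25557 loci tested in both tissues, limma's interaction called 0 (smallest adjusted p 0.0655), with 2040 at an unadjusted p under 0.05 (1004 with the higher change in root, 1036 with the higher change in leaf). As sets, phenylpropanoid genes (median difference 0.42, camera adjusted p = 0.000134) and heat shock proteins (0.15, 0.0396) differed toward root and aquaporins (-0.14, 0.00735) toward leaf, each with adjusted p = 0.872 with an estimated correlation. With 1 library left out, limma called 1 to 20 loci, the 20 without zinc-deficient root replicate 1.

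Adjusted over the list alone, Glyma.13G004400, Glyma.15G262800, Glyma.20G063100, Glyma.08G164400, Glyma.06G052000, Glyma.19G228400, Glyma.09G036400, Glyma.08G174700, Glyma.19G231000 and the locus of Glyma.03G233900 rose in both tissues. Past the all-gene threshold, 0 loci were shared, since limma called 0 in root. At an unadjusted p under 0.05, 158 loci were higher in both among 1205 in leaf and 1389 in root, where independent lists would share 65.5, and 51 were lower in both among 628 and 778, where independent lists would share 19.1. The authors' deposited table called 282 of 27079 loci rising in leaf and 513 in root, with 58 in both against 5.34 for independent lists (exact hypergeometric p = 1.1e-42). It called 188 falling in leaf and 144 in root, with 12 in both against 1 (exact hypergeometric p = 4.11e-10). In opposite directions, the authors' deposited table called 15 loci falling in leaf and rising in root against 3.56 (exact hypergeometric p = 3.3e-06), and 3 rising in leaf and falling in root against 1.5 (exact hypergeometric p = 0.19). Fitted on all 8 libraries, limma called 7 loci in both tissues, among them iron regulated transporter 3 (Glyma.06G052000) and nicotianamine synthase 2 (Glyma.19G228400).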

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

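The tests of leaf tissue, of reads taken over from other carbonic anhydrases and of both copies of carbonic anhydrase 1 were chosen after the result was seen; the test of the difference between tissues was planned.

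The items here drew attention because leaf and root differed in their response, either by the camera test of the difference or because both deficient libraries lay beyond both sufficient libraries in opposite directions in the 2 tissues. By the test of the list, root minus leaf, the median difference was 0.42 (0.4192) for phenylpropanoid and isoflavonoid synthesis, 0.15 (0.1507) for heat shock proteins and -0.14 (-0.1386) for aquaporins. Their adjusted p was 0.000134, 0.0396 and 0.00735 at the preset correlation, and adjusted p = 0.872 with an estimated correlation for each. For single genes the interaction was tested in limma with Benjamini-Hochberg adjustment and none passed. The difference of log2 fold changes was 5.79 for Glyma.05G007100 (5.795, adjusted p = 0.0902) and 5.33 for Glyma.19G007700 (5.331, adjusted p = 0.222), both carbonic anhydrase 1. It was 4.71 for the joined resistance-gene locus of Glyma.16G158900, Glyma.16G159000 and Glyma.16G159100 (adjusted p = 0.723), where 1 sufficient leaf library at 294 FPKM made the leaf fold. The iron superoxide dismutases Glyma.10G193500 and Glyma.20G196900 had 1.63 (adjusted p = 0.489) and 1.03 (adjusted p = 0.435), and the copper/zinc superoxide dismutase Glyma.03G242900 had -1.96 (-1.962, adjusted p = 0.373). The chalcone synthase Glyma.11G011500 had 1.21 (1.213, adjusted p = 0.404), SPX domain gene 2 Glyma.13G166800 had 1.19 (adjusted p = 0.373), and the heat shock proteins Glyma.11G140500 and Glyma.18G074100 had 0.92 (0.923, adjusted p = 0.487) and 0.51 (0.5073, adjusted p = 0.605).

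Carbonic anhydrase 1 in root was weighed further, since it is an abundant leaf transcript. The 2 copies weighed were chosen as loci of that description with a root log2 fold change above 1, so their rise is no separate test. Leaf tissue mixed into the deficient root samples would have raised photosystem genes with it, but over 130 photosystem loci the deficient libraries showed -0.0849 and 0.0487 of the rise that the carbonic anhydrase needed, which argues against it. Reads taken over from other carbonic anhydrases would leave the family's total unchanged, but the summed FPKM of all carbonic anhydrases rose by 0.864 and 0.928 of the rise of the 2 copies, which argues against that source but says nothing on reads shared between the 2 copies. Both copies stayed past the threshold adjusted over the list alone with either deficient root library left out (highest limma adjusted p 0.0118, the other 0.011). A response of carbonic anhydrase 1, at 1 copy or at both, to zinc deficiency may be offered as a hypothesis, with reads shared between the copies, the transcript XLOC_041148 at the coordinates of Glyma.05G007100, the unknown depth and the separate origin of the samples left open.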

How the results depend on the processing

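Restricting the tests to status OK or to spans of at least 500 bp was chosen after the data were seen; all other settings were planned. No label says that the replicate numbers pair the libraries. Deviations of same-numbered libraries correlated at -0.013 in leaf and -0.021 in root, which shows no shared deviation but cannot exclude a pairing. The block is given as a number only. For counts of loci past the threshold in limma with Benjamini-Hochberg adjustment, leaf moved from 35 to 11 at a mean FPKM of at least 5, to 19 without a filter, to 20 with the replicate block, to 15 with status OK and to 22 with spans of at least 500 bp. The FPKM, status and span settings tested fewer loci, the fit without a filter more, and the block the same loci. It fell to 0 (range 0 to 0) with any 1 library left out, a setting in which the lone library of a group is assumed to vary like the others. Pseudocounts, both scalings, both other eBayes settings and the fit on all 8 libraries kept it within 1.5 times. Root moved from 0 to 1 with the pseudocount of 0.1, to 1 at a mean FPKM of at least 5, to 1 under quantile normalisation, to 1 with robust eBayes, to 1 with status OK, to 1 with spans of at least 500 bp and to 25 in the fit on all 8 libraries. With 1 library left out it ranged from 0 to 157; the 157, without zinc-deficient root replicate 1, held 148 rising loci, 68 of them spanning under 500 bp. The tissue difference moved from 0 to 2 with the pseudocount of 0.1 and to 1 to 20 with 1 library left out. Loci called in both tissues moved from 0 to 7 in the fit on all 8 libraries and to 0 to 1 with 1 library left out. The cause was not tested.

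Lists past the threshold with camera moved in leaf from 7 to 0 with an estimated correlation, to 0 with fry, and to 3 to 7 with 1 library left out. In root they moved from 4 to 0 with an estimated correlation, to 0 with fry, to 7 at a mean FPKM of at least 5, to 7 under median-ratio scaling and to 7 in the fit on all 8 libraries. For both tissues the fry counts are those of its directional test. The replicate block left the root, difference and shared counts of loci past the threshold over all genes at 0 and the root list count at 4. Among list medians, 1 reversed, leaf median log2, leaf photosynthetic cells (photosystem and antenna genes), which was -0.19: the values with 1 library left out ran from -0.4696 without zinc-deficient leaf replicate 1 to 0.13 without zinc-deficient leaf replicate 2; the cause was not tested. Of 38 named leaf genes past a threshold, 5 to 11 stayed past it with 1 library left out, and of 27 in root 11 to 16 did; with the replicate block 20 and 15 did; none changed direction. Scaling moved the median of all genes by less than 0.1 log2 units. Depth cannot be read from FPKM, so its limit on low genes remains unknown.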

Other observations

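The tests of short loci, of fragment steps, of the zinc lists across tissues and of ferric iron binding genes were chosen after the results were seen; the fit on all 8 libraries was planned. Genes singled out here that the fixed rule did not take were chosen after their values were seen.

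In the fit on all 8 libraries, limma with Benjamini-Hochberg adjustment called 7 loci rising in both tissues. Besides the transporter and the nicotianamine synthase already named, these were a prolyl oligopeptidase (Glyma.14G222700; 122 and 189.8 FPKM in deficient against 4.41 and 7 FPKM in sufficient leaves, 287 and 283 against 32.1 and 22.5 FPKM in roots), a UDP-glycosyltransferase (Glyma.18G265900), a myb-like transcriptional regulator (Glyma.09G113100), the unannotated Glyma.11G142200, and XLOC_041148 (34.1 and 53.3 against 0.819 and 2.03 FPKM in leaves, 41.5 and 31.7 against 0.146 and 0.179 FPKM in roots). The myb-like gene stood at 3.3 and 4.29 against 0.208 and 0.112 FPKM in leaves and at 8.78 and 8.02 against 0.33 and 0.252 FPKM in roots. Glyma.11G142200 (256 bp, status NOTEST in leaf) had 4.08 and 3.18 FPKM in deficient leaves and was listed at 0 in both sufficient leaves. In roots it stood at 22.9 and 37.3 against 1.825 and 2.33 FPKM. In root that fit also called a PQ-loop protein (Glyma.01G178800; log2 3.94, adjusted p = 0.00764), a bHLH protein (Glyma.12G196700; 2.03, adjusted p = 0.0227), a MATE efflux protein (Glyma.09G102800; 1.66, adjusted p = 0.0307) and a CHY-type zinc finger protein at the locus of Glyma.14G130600 (1.56, adjusted p = 0.0196). In leaf it called glucose-6-phosphate/phosphate translocator 2 (Glyma.15G105900; 4.16, adjusted p = 0.0259).

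Among the 12 loci that the authors' deposited table called falling in both tissues were 5 described as cytochromes P450, a family chosen after its values were seen and not tested against its share of all loci. In the authors' deposited table the log2 fold changes in leaf and root were -1.17 and -4.25 for CYP82C4 (Glyma.15G203500), -1.14 and -3.69 for CYP81D3 (Glyma.15G156100), -1.58 and -3.04 for Glyma.11G062500, -1.93 and -1.31 for Glyma.11G062600, and -1.89 and -2.08 for Glyma.16G195600. CYP82C4 is among the Arabidopsis loci fixed for the iron deficiency response, but members were matched by description alone. The 0 members past the threshold on that list in either tissue thus do not cover Glyma.15G203500. The ferritin list, matched by description, had 0 members past the threshold in either tissue. Of its 6 members tested in leaf, the authors' deposited table called 1 falling and 0 rising. The descriptions spell ferritin 1 as ferretin 1, and the planned Arabidopsis best hits were not applied. Its 4 copies thus fell outside the ferritin list as tested, and the 0 above does not cover them. The authors' deposited table called all 4 rising in leaf (1.76, 1.325, 1.23 and 1.17) and Glyma.01G124500 falling in root (-1.01). None of the 4 passed in limma over all genes (Benjamini-Hochberg adjusted p = 0.315 to 0.562 in leaf, and 0.503 for Glyma.01G124500 in root). Their unadjusted p in limma ran from 0.0019 to 0.0116 in leaf, and they were not adjusted over the list alone. They were chosen after their values were seen. In the libraries, Glyma.01G124500 read 377 and 299 FPKM in deficient against 69 and 129 FPKM in sufficient leaves, and 5.11 and 8.47 against 14.6 and 13.3 FPKM in roots. Over 10 genes of the term ferric iron binding, the interaction in camera tested whether leaf and root differ, not whether they respond in opposite ways: the median difference was -0.798, with p = 2.42e-06 at the preset and p = 0.037 with an estimated correlation. The term was picked from more than 400 after the tissues' values were seen, and 0 terms passed with an estimated correlation after adjustment (9 of 406 in leaf and 30 of 420 in root passed at the preset), so the difference may be a product of that choice. Within the tissues the term had adjusted p = 0.996 in leaf and adjusted p = 0.877 in root with an estimated correlation, and whether the tissues respond in opposite ways stays open.

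Across the 59 genes of the 3 zinc lists tested in both tissues, the leaf and root log2 fold changes were compared to test whether the lists respond alike. Spearman's rho was 0.538 (permutation p = 4e-05) and Pearson's r 0.765 (permutation p = 1e-05, the smallest that 100000 resamples can give). Without the 2 genes farthest from the leaf median, r was 0.78 and rho 0.489. Other genes with large rises in both tissues, such as Glyma.20G063100 and Glyma.08G164400, stayed in. Whether the remaining genes of the lists respond alike was thus not tested. Genes are not independent replicates, and over all 25557 genes r was 0.0832.

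Short loci were frequent among the rising root calls of the authors' deposited table, 163 of 776. In zinc-deficient root, replicate 2 exceeded replicate 1 by a median log2 of 1.75 over tested loci spanning under 300 bp and by 0.0159 over loci above 2000 bp, while zinc-sufficient root gave 0 for the short loci; a library effect on short loci in replicate 2 is thus a candidate explanation. Over the 163 calls, the median log2 of replicate 1 over the sufficient mean was 0.438 (bootstrap interval 0.282 to 0.57), against 0.799 over the 613 longer rising calls. The calls already used replicate 1 and the sufficient libraries, so a value above 0 is favoured by their selection and is no evidence of a response. Whether zinc deficiency also raises some of these loci stays open.

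Rising leaf calls at loci listed at 0 in both sufficient leaves numbered 20. If each rested on 1 to 3 fragments per library, the 2 deficient libraries would stand in ratios of small whole numbers times a base ratio, fitted at 1.285 from 42 uncalled loci: 80% did (16 of 20, within 3%), against 13.8% of 10439 long, well measured loci, which is what such small numbers would give. This test first covered all 29 calls with a group at 0 (55.2% against 17.3% of long loci) and was narrowed to the rising calls after the 9 falling calls gave 0 of 9, with a base ratio taken from only 25 loci; for the falling calls it gives no such evidence. A response to zinc deficiency remains open: of 11 of the 20 loci tested in root, 1 moved the same way there at an unadjusted p under 0.05. Low fragment numbers may thus lie behind many of these 20 calls, while Glyma.13G004400 and Glyma.06G052000 are outside this group.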
